A study of Caenorhabditis elegans with 12 samples.

How the data were processed

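RNA was measured in whole hermaphrodites of 4 genotypes with 3 libraries each, 12 in all. Per the labels, synchronised worms were grown on OP50 at 20 °C and collected in independent harvests, RNA was isolated with an acid phenol reagent (RNAiso plus), and libraries were sequenced in pairs on an Illumina NovaSeq. The strains were N2, the dis-3(L75Q) strain VC40130, the eat-2(ad1116) strain IJ173 and the double mutant strain IJ2290. The deposited values are expected counts per gene, estimated numbers of fragments that are scaled neither to depth nor to gene length, per the file headers. The submitters' processing notes name STAR 2.7.0e, RSEM 1.3.1 and the genome builds WBcel235 and ce11. The annotation used for counting, any trimming, the RNA selection and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Each file holds 46934 gene entries, of which 46924 matched the Ensembl release 115 annotation of WBcel235 by identifier and 44113 had a symbol there. Coordinates are 1-based and come from that annotation.

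Expected counts that need not be whole arise where reads fit several genes. Between 93.4% and 93.8% of the values above 0 were exactly whole (tolerance 0) in each library, and all were rounded to whole numbers. Members of pairs and families with similar sequences (fat-6 and fat-7, vit-3 and vit-4, the pud, clec, nspc and col families) can exchange reads and are uncertain for that reason. All 634 tRNA gene entries held 0 counts in all libraries, so tRNAs and their fragments were not measured here. Library totals ran from 31812386 to 32773817 counts, with 18236 to 18851 genes above 0 and scaling factors (trimmed mean of M-values, TMM) of 0.9284 to 1.139. A gene with 0 counts was given a floor of 3 counts per library. Intervals and floors cover counting error only.

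Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust estimation, TMM scaling, filterByExpr by genotype, all 12 libraries in 1 fit with a term for genotype alone), which left 16259 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The comparisons were each single mutant against wild type, the double mutant against each single mutant and against wild type, and the interaction. All p-values are two-sided. CPM values use TMM-scaled library sizes. Gene lists, 32 of them with at least 5 measured members, were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, adjusted over the 32 lists), beside camera with an estimated correlation and fry. Measures with 1 value per library were compared with exact permutation tests, 3 libraries against 3, where the smallest possible p is 0.1. Correlations of log2 fold changes are across genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

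The groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those said to be added later. The rule named dis-3 and eat-2. It then named the 6 genes with the largest rise and the 6 with the largest fall among called genes with a gene-class name, a mean of at least 5 CPM and groups that did not overlap, for both single mutants against wild type and for the double mutant against eat-2(ad1116). It named 4 and 4 for the other comparisons and the interaction. From each list called by camera or with at least 3 called members it named the 2 called members with the smallest p. Genes of the chromosome V interval and genes without a gene-class name were chosen after their values were seen.

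The test was checked on simulated counts with the means and sizes of these libraries. For dis-3(L75Q) against wild type it recovered 10%, 38%, 80% and 88% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold (50 genes of each size among 16259), with 5 false calls among 113. For the interaction it recovered 2%, 12%, 54% and 80%, with 5 false among 79. In 20 simulated data sets without effects camera called 0 lists. Their genes were drawn without correlation, so this does not test lists whose genes move together (estimated correlation up to 0.963 here). The counts for the gene tests were drawn in the same way, without shared variation along stage. Their recovery and false calls may therefore not hold for these libraries.

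Alternatives were other scalings (DESeq2-type size factors, none beyond library totals), other tests (DESeq2 1.42.0, limma-voom), no filter or a stricter one, a fit of the 6 libraries compared, a block for the replicate number, an adjusted p under 0.01, a minimum of 2-fold, and each library left out in turn. Chosen after seeing the data were the stage score as a covariate and the omission of the 3 libraries that lay apart on it. Each file holds a gene identifier and an expected count and no other column.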

Results

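Whole-body RNA of Caenorhabditis elegans hermaphrodites, taken as adults before the start of egg laying, was sequenced for 4 genotypes with 3 libraries each. The genotypes were wild type, the single mutants dis-3(L75Q) and eat-2(ad1116), and the double mutant that carries both alleles. All animals were grown at 20 °C on OP50, the Escherichia coli strain used as standard food, and the labels state 3 independent harvests. DIS-3 is a ribonuclease of the RNA exosome, the complex that trims and degrades RNA. EAT-2 is an acetylcholine receptor subunit of the pharynx, and eat-2 mutants, which eat slowly, are a common genetic model of dietary restriction. The design compares transcript levels with each allele and with both, in a study of DIS-3 and lifespan. It sets the response to eat-2(ad1116) with dis-3(L75Q) beside that without it. All libraries of a genotype came from the same strain, so the comparisons are between strains. What an allele does by itself cannot be told apart from other variants of its strain. Effects named after an allele below are differences between such strains. Libraries held 31812386 to 32773817 counts, and 16259 genes had enough counts to be tested. Group values are CPM (normalised counts scaled to the library total) as mean ± SD over 3 libraries, and log2 fold changes are given ± SE with adjusted p-values from edgeR.

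The RNA of the mutated genes themselves was present in all genotypes. The dis-3 transcript (chromosome IV, 10097202 to 10106523) lay at 182 ± 12 CPM in wild type (libraries 168 to 189), 185 ± 4 in dis-3(L75Q) (182 to 190), 161 ± 8.1 in eat-2(ad1116) (153 to 169) and 168 ± 7.2 in the double mutant (161 to 175), and no comparison of it passed the test. The eat-2 transcript (chromosome II, 14166878 to 14171658) was near the detection limit in whole animals, at 0.625 ± 0.13, 0.624 ± 0.15, 0.439 ± 0.29 and 0.279 ± 0.013 CPM in the same order (6 to 24 counts per library), and did not pass the test either. The name dis-3(L75Q) gives an amino acid change and the eat-2 transcript had few counts, so neither level checks the labels.

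The libraries varied most along genes of the molt and of egg formation. The first principal component held 50.3% of the variance, of which 53.2% lay between genotypes. Its ends were marked by genes of the molt and new cuticle (mlt-11, dpy-7, dpy-9, lpr-3, fbn-1) and by yolk protein genes (vit-3, vit-4, vit-5). A stage score, the mean log2 CPM of 40 molting genes minus that of 39 oocyte and eggshell genes, was -1.76 ± 1.64 in wild type, 0.67 ± 1.31 in dis-3(L75Q), 0.63 ± 1.61 in eat-2(ad1116) and 0.45 ± 0.3 in the double mutant. Wild type replicate 2 (0.082), dis-3(L75Q) replicate 3 (-0.819) and eat-2(ad1116) replicate 1 (-1.237) lay apart from the other libraries of their genotypes. The difference from wild type had an exact two-sided permutation p of 0.2 for dis-3(L75Q), 0.2 for eat-2(ad1116) and 0.1 for the double mutant, where 0.1 is the smallest value that 3 against 3 libraries can give.

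**Figure D1:**
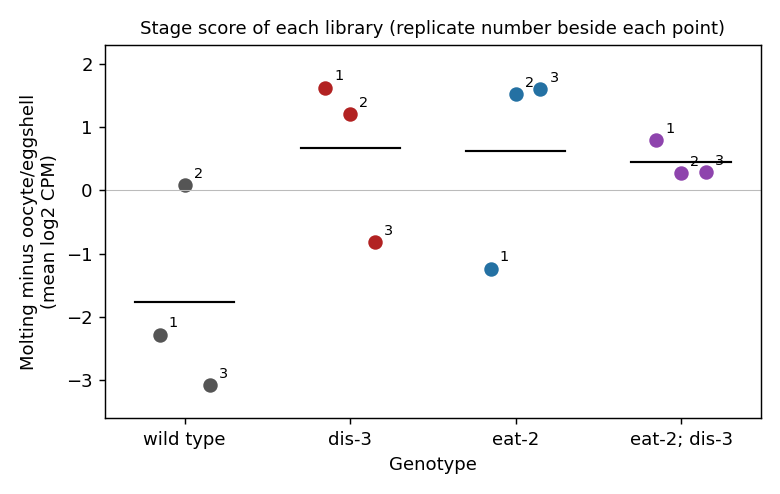
Stage score of each library (molting minus oocyte and eggshell genes, mean log2 CPM, y axis) by genotype, with points for libraries, their replicate numbers and a line for the mean of 3. Wild type spans -3.076 to 0.082 and the double mutant 0.272 to 0.793.

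In dis-3(L75Q) against wild type, the fatty acid desaturase gene fat-6 fell while fat-7 and fat-5 rose. The stearoyl-CoA desaturase gene fat-6 (chromosome IV, 11913692 to 11915687) fell from 449 ± 69 to 128 ± 14 CPM, which is 3.52-fold lower (log2 -1.81 ± 0.14, adjusted p = 0.00012). The sister gene fat-7 (chromosome V, 7151353 to 7153146) rose from 134 ± 10 to 666 ± 140 CPM (log2 2.32 ± 0.15, adjusted p = 3.6e-05), and the palmitoyl-CoA desaturase gene fat-5 (chromosome V, 17725004 to 17726818) rose from 45.1 ± 11 to 153 ± 21 CPM (log2 1.76 ± 0.17, adjusted p = 0.00076). Because fat-6 and fat-7 have similar sequences, counting may split some of their reads, and their summed level was 583 ± 71 CPM in wild type and 794 ± 153 in dis-3(L75Q). Among called genes with a gene-class name and a mean of at least 5 CPM, the largest fall was that of hmt-1, which encodes an ABC transporter of heavy-metal tolerance, from 87.6 ± 3.2 to 9.32 ± 0.7 CPM (9.39-fold lower, log2 -3.23 ± 0.09, adjusted p = 2.5e-08). T24C12.3, a gene without such a name that was chosen after its values were seen, fell further (log2 -3.58 ± 0.23, adjusted p = 3.61e-05).

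Of the 16259 genes, 91 passed the test in dis-3(L75Q) against wild type, 52 higher and 39 lower, and 83 of them changed at least 2-fold. With the same limits on name and mean level, the largest other falls, with fat-6, were those of rnf-126 (6.4-fold), eri-12, a factor of RNA interference (5.5-fold), acdh-2, an acyl-CoA dehydrogenase gene (3.61-fold), and fbxa-108, an F-box gene (2.9-fold). The largest rises within these limits, with fat-7, were those of scb-1 (6.5-fold), cpt-4, of the carnitine palmitoyltransferase family (5.75-fold), irg-5, an infection response gene (5.01-fold), and the C-type lectin genes clec-3 (4.38-fold) and clec-52 (4.15-fold).

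Among the gene lists fixed before the data were examined, innate immune effectors had 7 of 100 members higher and 0 lower (17 higher and 2 lower when adjusted over the list alone), with dod-22 (3.64-fold, log2 1.87 ± 0.25) and clec-82 (3.2-fold, log2 1.68 ± 0.24) as examples. The list as a whole shifted up (camera adjusted p = 1.3e-05), with an adjusted p = 0.65 with an estimated correlation. Of 46 fasting response, lipase and beta-oxidation genes, 3 rose and 1 fell (13 and 3 adjusted over the list alone). These included cpt-3 (4.67-fold, log2 2.22 ± 0.37) and icl-1, the glyoxylate cycle gene (1.48-fold, log2 0.56 ± 0.1). Fatty acid synthesis and desaturation had 2 of 27 higher and 1 lower (6 and 1 over the list alone). Both lists shifted up by camera (adjusted p = 0.00035 and 0.024), with an adjusted p = 0.65 with an estimated correlation for each. Neither was called with the stage score as a covariate (adjusted p = 0.7 and 0.73). In the libraries apart on that score, dis-3(L75Q) replicate 3 and wild type replicate 2, the mean log2 levels from the average of all libraries were -0.11 and -0.1 for fasting genes and -0.02 and 0.02 for fatty acid synthesis. Cuticle collagens had 4 members higher and 147 not called (5 higher adjusted over the list alone) without a shift of the list (camera adjusted p = 0.15, and 0.76 with an estimated correlation). The stage covariate gave a shift up (adjusted p = 7.9e-08). The collagen gene col-36 went from 0.0739 ± 0.1 to 9.17 ± 3.9 CPM (adjusted p = 0.00069, log2 6.9, and 8.89 without wild type replicate 2) and col-123 from 0.835 ± 0.12 to 4.91 ± 1.3 CPM (adjusted p = 0.0051). Intestinal genes had 2 of 28 higher (2 over the list alone), fat-7 and pgp-1, a P-glycoprotein gene (2.4-fold, log2 1.27 ± 0.16). SKN-1 and detoxification targets had 1 of 41 higher, cyp-34A9 (2.11-fold), with 4 higher and 1 lower over the list alone, and DAF-16 targets had 2 of 38 higher, with 6 and 2 over the list alone.

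The molting, sperm, oocyte and eggshell, and germline lists shifted by camera in dis-3(L75Q) without calls of single genes. Molting genes had a median log2 change of 1.11 (35 of 40 positive), sperm genes -0.81, oocyte and eggshell genes -1.1 and germline genes -0.35, alongside the difference in stage score of 2.43. Neither edgeR, DESeq2 nor limma-voom called any of their members (0 in each), and 9 molting, 5 sperm, 4 oocyte and 17 germline genes had an unadjusted p under 0.05. Camera called 18 of the 32 lists, 11 up and 7 down, and 0 with an estimated correlation, where the lowest adjusted p = 0.65. Camera with the stage score as a covariate called 5 lists. By its construction the covariate removes the gap between molting and oocyte genes, but not a shift that both share. Of the 18, it called ribosomal proteins and body wall muscle, both in the opposite direction. The other 3 were collagens, up, and autophagy and lysosome (adjusted p = 4e-06) and oxidative phosphorylation (adjusted p = 0.00096), both down. The other lists called up were ribosomal proteins (median 0.14), heat shock response (0.21), SKN-1 and detoxification targets (0.47), intestine (0.25), body wall muscle (0.2), pharynx (0.31) and neurons (0.37). The other lists called down were ribosome biogenesis and RNA polymerase I (-0.08), RNA exosome and exonucleases (-0.13), Argonautes and small RNA factors (-0.17) and yolk proteins (-1.46). Adjusted over the list alone, heat shock response had 5 of 24 higher, pharynx 1 of 27 higher and zygotic embryo 1 of 12 lower. Of 83 ribosomal protein genes, 76 had a positive log2 change (median 0.08 without scaling), 1 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0.

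The remaining lists were not called in dis-3(L75Q) against wild type without that covariate. Their median log2 changes were 0.05 for translation initiation and elongation factors, 0.04 for aminoacyl-tRNA synthetases, 0.06 for the mitochondrial ribosome, 0.11 for oxidative phosphorylation, and 0.14 and 0.13 for the mitochondrial and endoplasmic reticulum stress responses. They were 0.3 for insulin-like peptides, -0.07 for autophagy and lysosome genes, -0.01 for the proteasome, -0.35 for 12 genes of the zygotic embryo, 0.18 for DAF-16 targets and 0.19 for collagens. Median and mean differed in sign for histones (0.04 and -0.14) and dietary restriction longevity factors (-0.03 and 0.04). The 25 lists without a single called gene in edgeR held 972 genes, of which 134 had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. The count of 91 genes was 338 with DESeq2, 30 in a fit of these 6 libraries alone, 1306 without wild type replicate 2, and 49, 58, 53 and 50 without wild type replicate 1, wild type replicate 3, dis-3(L75Q) replicate 1 and dis-3(L75Q) replicate 2. Calls for irg-5, clec-3, acdh-2, cyp-34A9, cpt-3, cpt-4 and clec-82 were lost without 1 or more of those last 4 libraries (highest adjusted p = 0.18). With the stage score as a covariate 74 genes were called, 35 higher and 39 lower, 56 of them among the 91. That fit lost 6 of 19 named calls. The log2 change went from 2.32 ± 0.43 to 1.48 ± 0.39 for irg-5 (adjusted p = 0.3), from 2.13 ± 0.36 to 1.35 ± 0.35 for clec-3 (0.27) and from -1.85 ± 0.32 to -1.41 ± 0.37 for acdh-2 (0.3), and cyp-34A9 (0.21), cpt-4 (0.058) and clec-82 (0.061) also missed the threshold.

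A stretch of chromosome V had almost no counts in the dis-3(L75Q) strains. It ran from 17339084 to 17551209 (212 kb, 82 annotated genes, WBcel235) and was singled out after its values were seen. Its 16 tested genes together had 1001, 847 and 953 counts in the wild-type libraries and 1756, 1868 and 1992 in the eat-2(ad1116) libraries. The dis-3(L75Q) libraries had 1, 3 and 0 counts and the double mutant libraries 0 each. Of the 16 genes, 12 passed the test in dis-3(L75Q) against wild type and 13 in the double mutant against eat-2(ad1116). F47H4.2 (17353323 to 17360204) was at least 42.6-fold lower in dis-3(L75Q) and at least 178-fold lower in the double mutant, taking 3 counts per library as the floor. The F-box gene fbxa-189 (17345214 to 17347781) was at least 37.5-fold and 54.6-fold lower. The nearest well-counted genes on either side, F31E9.3 (47 counts on average in wild type, 45 in dis-3(L75Q)) and C38D9.2 (49 and 45.7), did not pass the test. Chromosome V held 45 of the 91 called genes (49.5%, against 20.5% of tested genes, Fisher's exact test, adjusted p = 5.7e-09 over 18 tests of chromosome and comparison). It also held 30 of the 57 genes called in the double mutant against eat-2(ad1116) (52.6%, adjusted p = 3.4e-07) and 302 of the 1009 called in eat-2(ad1116) against wild type (29.9%, adjusted p = 3.1e-12). Fisher's test takes genes as independent, while 12 of the 45 and 13 of the 30 lie in the stretch. The p-values therefore overstate the evidence, and the chromosome was not tested without the stretch.

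**Figure D2:**
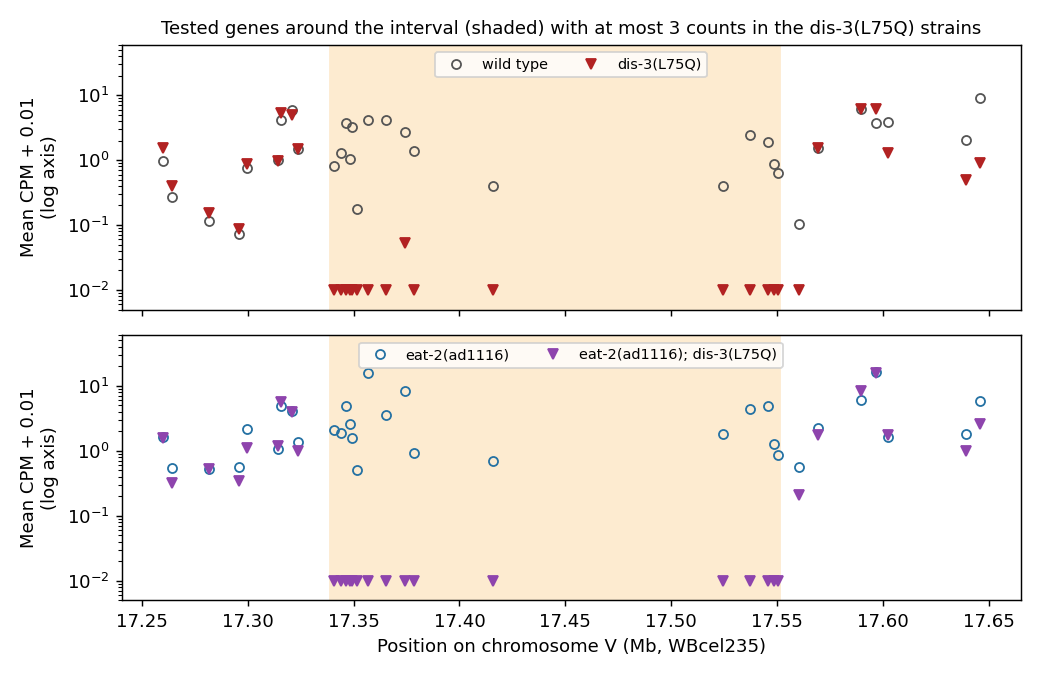
Mean normalised count (CPM + 0.01, log axis, 3 libraries per genotype) of each tested gene against its position on chromosome V in Mb, wild type and dis-3(L75Q) above, eat-2(ad1116) and the double mutant beneath. Inside the shaded 212 kb the 16 genes have at most 3 counts in any library with dis-3(L75Q), while the nearest well-counted genes on both sides keep theirs. Farther right, fbxa-192 is lower in both dis-3(L75Q) strains.

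In the double mutant against eat-2(ad1116), which measures dis-3(L75Q) in the other background, the desaturase genes fat-6, fat-7 and fat-5 moved as in the single mutant. The fat-6 level fell from 444 ± 68 to 136 ± 2.4 CPM (log2 -1.7 ± 0.14, adjusted p = 5e-04), fat-7 rose from 81.1 ± 5.2 to 482 ± 41 CPM (log2 2.57 ± 0.15, adjusted p = 3.4e-05) and fat-5 rose from 37.8 ± 4.1 to 138 ± 11 CPM (log2 1.87 ± 0.17, adjusted p = 0.00071). The genes eri-12 (6.6-fold) and rnf-126 (5.85-fold) fell and pgp-1 (2.59-fold), cyp-29A3, a cytochrome P450 gene (2.84-fold), lido-8 (2.44-fold) and pph-7 (2.43-fold) rose. Also lower were 3 transcripts that eat-2(ad1116) raised over wild type. The noncoding RNA tts-1 went from 194 ± 29 to 66.9 ± 11 CPM (log2 -1.53 ± 0.18, adjusted p = 0.0028), the lysosomal lipase gene lipl-1 from 34.7 ± 9.2 to 6.52 ± 0.94 (log2 -2.41 ± 0.25, adjusted p = 0.0013) and lipl-2 from 23.1 ± 2.1 to 7.51 ± 1 (log2 -1.62 ± 0.24, adjusted p = 0.015).

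This comparison called 57 genes, 25 higher and 32 lower. Cuticle collagens had 4 members higher and 147 not called (5 higher adjusted over the list alone), and the list shifted up (median 0.42, camera adjusted p = 1.3e-13, adjusted p = 0.47 with an estimated correlation). Among them col-36 went from 0.0104 ± 0.018 to 9.68 ± 1.2 CPM, a ratio of 974 with a 95% counting interval of 174 to 38500 on 1 count in eat-2(ad1116) (log2 9.45, and 11.29 without eat-2(ad1116) replicate 2), and col-123 from 0.107 ± 0.068 to 2.43 ± 0.5 CPM (adjusted p = 0.00071). Fatty acid synthesis had 2 of 27 higher and 1 lower (3 and 1 over the list alone), and fasting response genes had 2 of 46 higher and 2 lower (8 and 7 over the list alone), with icl-1 higher by 1.61-fold (log2 0.69 ± 0.1). The flavin monooxygenase gene fmo-2, an innate immune list member, went from 2.06 ± 0.87 to 0.31 ± 0.081 CPM (log2 -2.72 ± 0.41, adjusted p = 0.019). Camera called 7 lists. Collagens, sperm (median 0.49) and the proteasome (0.09) were up, and histones (-0.09), dietary restriction longevity factors (-0.08), autophagy and lysosome genes (-0.13) and innate immune effectors (-0.13) were down. None was called with an estimated correlation (0 of 32, lowest adjusted p = 0.47). The stage covariate gave 9 lists, 6 of the 7 in the same direction (histones lost, adjusted p = 0.13) and yolk proteins, molting and oocyte genes, all up. The 26 lists without a called gene in edgeR held 1013 genes, of which 38 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0.

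The 2 measures of the dis-3(L75Q) effect share no library, but each genotype was 1 strain. A variant carried by both dis-3(L75Q) strains would repeat in both measures and cannot be told apart from the allele. Of the 52 genes higher in dis-3(L75Q), 12 were also higher in the double mutant against eat-2(ad1116) (0.08 for independent lists), and of the 39 lower, 21 were also lower (0.0768 for independent lists), while 0 were called in opposite directions. The 12 included fat-5, fat-7, pgp-1, col-36, col-123, cpt-3 and icl-1, and 14 of the 21 lie on chromosome V, 12 of them inside the 212 kb stretch, which leaves 9 of the 21 outside it. Among the 9 is fbxa-192, which lies near the stretch. Over the 91 genes called in dis-3(L75Q), 84.6% had the same sign in the double mutant. Across all 16259 genes, which are not independent replicates, the 2 effects had a Pearson r of 0.298 and a Spearman rho of -0.033, and r was -0.151 without eat-2(ad1116) replicate 1. The count of 57 genes was 174 with DESeq2, 31 in a fit of these 6 libraries alone, 255 without eat-2(ad1116) replicate 1, 33 and 31 without eat-2(ad1116) replicates 2 and 3, and 30, 29 and 29 without double mutant replicates 1, 2 and 3. Calls for cyp-29A3, pph-7, lipl-2, icl-1 and fmo-2 were lost without 1 or more of those last 5 libraries (highest adjusted p = 0.24). With the stage score as a covariate the count was 176, 107 higher and 69 lower, with all 57 among them.

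In eat-2(ad1116) against wild type, the largest rise among called genes with a gene-class name and a mean of at least 5 CPM was that of tts-1 (chromosome X, 1504131 to 1504841), a noncoding RNA found with ribosomes, from 2.55 ± 0.58 to 194 ± 29 CPM (75.9-fold, log2 6.25 ± 0.22, adjusted p = 3e-07). The lysosomal lipase genes lipl-1 (26.8-fold, log2 4.74 ± 0.28) and lipl-3 (13.3-fold, log2 3.73 ± 0.24), the lipase gene lips-6 (16.9-fold) and the lectin gene clec-61 (14.8-fold) followed, with the collagen gene col-41 (33.3-fold, log2 5.06 ± 0.93). The col-41 level ran from 9.16 to 170 CPM over the eat-2(ad1116) libraries, and with the stage score as a covariate its call was lost (log2 3.01 ± 1.13, adjusted p = 0.18). The yolk protein gene vit-1 fell from 245 ± 100 to 16.7 ± 12 CPM (14.7-fold lower, log2 -3.87 ± 0.72, adjusted p = 0.013). The near-identical pair vit-3 (26.4-fold lower) and vit-4 (19.2-fold lower), whose reads counting can split, fell with it. These calls were lost without eat-2(ad1116) replicate 2 or 3 and, for vit-3 and vit-4, also without wild type replicate 1 or 3 (highest adjusted p = 0.072, 0.12 and 0.14 in the order vit-1, vit-3 and vit-4). Without eat-2(ad1116) replicate 1 the log2 change went from -3.87, -4.72 and -4.27 to -4.62, -7.03 and -6.7 in that order. They passed the threshold with the stage score as a covariate, at a log2 change of -2.61, -3.5 and -3.01, where the score itself differed by 2.38. Other falls were those of col-126 (10.6-fold), irg-5 (6.53-fold) and the ammonium transporter gene amt-1 (5.17-fold). The col-126 call was lost without wild type replicate 1 or 3 or eat-2(ad1116) replicate 2 or 3 (highest adjusted p = 0.13). Its log2 change went from -3.4 to -4.84 without eat-2(ad1116) replicate 1 and to -2.13 with the stage covariate (adjusted p = 0.0066).

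In the fit of all 12 libraries this was the comparison with the most calls, 1009 genes, 664 higher and 345 lower. In fits of the 6 libraries compared it had 84 and the double mutant against wild type 1432. Without scaling beyond library totals the share that was higher went from 65.8% to 86.5%. With the stage score as a covariate 860 genes were called, 309 higher and 551 lower, 470 of them among the 1009, and of 38 named calls 5 were lost (col-41, ins-11, ins-7, sqst-1 and epg-9, highest adjusted p = 0.18). Innate immune effectors had 24 of 100 higher and 5 lower (34 and 9 adjusted over the list alone), with the lysozyme gene lys-7 rising from 51.2 ± 5.8 to 214 ± 6.7 CPM (adjusted p = 1.4e-05). DAF-16 targets had 10 of 38 higher and 3 lower (14 and 4 over the list alone), and SKN-1 and detoxification targets 5 of 41 higher and 5 lower (7 and 7 over the list alone). The glutathione S-transferase genes gst-4 (3.16-fold, log2 -1.66 ± 0.14) and gst-10 (2.42-fold, log2 -1.27 ± 0.14) were among the falls. Fasting response and lipase genes had 5 of 46 higher and 2 lower (9 and 4 over the list alone), and yolk proteins 3 of 6 lower (6 over the list alone). Neuronal genes had 11 of 39 higher (30 over the list alone), among them the neuropeptide genes flp-1 (2.06-fold, log2 1.04 ± 0.18) and flp-9 (2.01-fold, log2 1 ± 0.18). Pharynx genes had 3 of 27 higher (14 over the list alone), among them phat-6 (2.78-fold, log2 1.47 ± 0.23). In the libraries apart on the stage score, eat-2(ad1116) replicate 1 and wild type replicate 2, the mean log2 levels from the average of all libraries were close, at -0.14 and -0.17 for neurons and -0.09 and -0.2 for pharynx, so the other libraries held most of the rise. Both lists were called up by camera with the score as a covariate (adjusted p = 5e-06 and 0.0011). An estimated correlation without it gave an adjusted p = 0.53 and 0.47. With the score, innate immune effectors (adjusted p = 0.063), DAF-16 targets (0.066) and fasting response genes (0.055, turned down) lost their camera calls. Yolk proteins (6.7e-07, down) and insulin-like peptides (0.023, up) kept theirs. Insulin-like peptides had 2 of 24 higher (4 over the list alone), ins-11 (4.9-fold, log2 2.29 ± 0.48) and ins-7 (2.12-fold, log2 1.08 ± 0.23).

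The proteasome had 12 of 33 members lower in eat-2(ad1116) (28 adjusted over the list alone, the list at adjusted p = 0.1 with an estimated correlation), with pas-2 (1.26-fold, log2 -0.33 ± 0.07) and rpn-12 (1.27-fold, log2 -0.34 ± 0.07) as examples, and 0 lower without scaling, where the median went from -0.25 to -0.16. Ribosome biogenesis and RNA polymerase I had 8 of 36 lower (19 over the list alone, 2 without scaling, the list at adjusted p = 0.3 with an estimated correlation), among them rpoa-2 (1.32-fold, log2 -0.4 ± 0.07). The mitochondrial ribosome had 6 of 66 lower (8 over the list alone, 1 without scaling), among them mrps-23 (1.36-fold), and aminoacyl-tRNA synthetases 1 of 20, kars-1 (1.43-fold), with 9 over the list alone. Translation factors had 2 of 45 lower (2 over the list alone), iff-1 (1.61-fold) and eif-2A (1.25-fold), and ribosomal proteins 2 of 83 (0 over the list alone, 3 with an unadjusted p under 0.05, 3 by DESeq2, 2 by limma-voom), with a median of -0.02 that was 0.05 without scaling. Cuticle collagens had 3 members higher, 9 lower and 139 not called (5 higher and 10 lower over the list alone), with col-68 (2.91-fold) and col-123 (7.46-fold) among the falls. Fatty acid synthesis had 2 of 27 higher and 2 lower (2 and 2 over the list alone), with fat-2 higher (1.62-fold, log2 0.7 ± 0.12) and fat-7 lower (1.65-fold, log2 -0.72 ± 0.15). Autophagy and lysosome genes had 3 of 48 higher and 1 lower (4 and 1 over the list alone), among them sqst-1 (1.58-fold, log2 0.66 ± 0.13), and histones 2 of 68 higher (21 higher and 8 lower over the list alone).

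Camera called 19 of the 32 lists in eat-2(ad1116) against wild type, 7 up and 12 down. The lists up were DAF-16 targets, insulin-like peptides, fasting response, innate immune effectors, molting, pharynx and neurons, with an adjusted p = 0.47 to 0.73 with an estimated correlation. The lists down were translation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, RNA exosome, Argonautes, mitochondrial ribosome, yolk proteins, proteasome, collagens, sperm, oocyte and germline, with an adjusted p = 0.1 for the proteasome, 0.3 for ribosome biogenesis and 0.47 to 0.73 for the others with an estimated correlation. Camera with the stage score as a covariate called 18 lists, 11 of them among the 19. Of these 10 kept their direction and germline genes changed theirs. The other 7, all down, were ribosomal proteins, oxidative phosphorylation, endoplasmic reticulum stress, SKN-1 targets, fatty acid synthesis, intestine and body wall muscle. Of the 19, DAF-16 targets, innate immune effectors, RNA exosome and sperm lost the call with their direction unchanged. Fasting response, molting, Argonautes and oocyte genes lost it and turned direction. The 10 lists without a called gene in edgeR, which included sperm (median -0.94), oocyte and eggshell (-0.93), germline (-0.27) and molting (0.51), held 367 genes, of which 77 had an unadjusted p under 0.05, DESeq2 called 18 and limma-voom 1. The count of 1009 genes was 84 in a fit of these 6 libraries alone, 2284 with DESeq2, 1714 without scaling, 2460 and 6161 without wild type replicate 2 and eat-2(ad1116) replicate 1, and 316, 396, 301 and 298 without wild type replicates 1 and 3 and eat-2(ad1116) replicates 2 and 3. Of 38 named calls, 15 held with any library left out, among them tts-1, lipl-1, lipl-3, lips-6, clec-61, irg-5, amt-1, lys-7, gst-4 and flp-1, and 23 were lost without 1 or more of those last 4 libraries (highest adjusted p = 0.2).

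In the double mutant against dis-3(L75Q), which measures eat-2(ad1116) in the other background, tts-1 rose from 3.55 ± 0.3 to 66.9 ± 11 CPM (18.8-fold, log2 4.23 ± 0.2, adjusted p = 3.6e-06) and lipl-3 from 1.7 ± 0.47 to 11 ± 1.6 (6.48-fold, log2 2.7 ± 0.23, adjusted p = 0.00021). The hmt-1 level rose from 9.32 ± 0.7 to 71.3 ± 3.2 CPM (7.65-fold, log2 2.94 ± 0.09, adjusted p = 6.1e-08) and cyp-37B1 rose 6.7-fold (log2 2.74, and 3.37 without dis-3(L75Q) replicate 3). The immune genes irg-5 (21.5-fold), dod-24 (12-fold) and clec-3 (11.3-fold) fell, as did pud-4 (7.52-fold), which has a near-identical copy. In all, 202 genes passed the test, 89 higher and 113 lower, and the share that was higher went from 44.1% to 60% without scaling, which moves the median gene by 0.12. Innate immune effectors had 9 of 100 higher and 8 lower (16 and 18 adjusted over the list alone), DAF-16 targets 6 of 38 higher and 2 lower (7 and 5), SKN-1 targets 4 of 41 lower (4 higher and 11 lower), fasting response genes 5 of 46 higher and 2 lower (7 and 5) and the mitochondrial ribosome 1 of 66 lower (23). Camera called 15 lists, 4 up and 11 down, and 0 with an estimated correlation (lowest adjusted p = 0.12, for the proteasome). The 8 genes named by size held with any library left out, while the count was 608 with DESeq2, 91 and 106 without dis-3(L75Q) replicates 2 and 1, and 103, 74 and 75 without double mutant replicates 1, 2 and 3. The stage covariate gave 768 genes, 340 higher and 428 lower, with all 202 among them. It gave 16 lists by camera, the 15 in the same direction and oocyte and eggshell genes up (adjusted p = 0.023).

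Set side by side, the eat-2(ad1116) effects with and without dis-3(L75Q) had the same sign for 95% of the 1009 genes called in eat-2(ad1116) against wild type (Pearson r 0.788 across genes, total least squares slope 0.57). For the 202 genes called in the double mutant against dis-3(L75Q) the slope was 1.05 (r 0.875), so the slope depended on the comparison on which the genes were chosen. Of 664 higher in eat-2(ad1116), 79 were also higher in the double mutant against dis-3(L75Q) (3.63 for independent lists), and of 345 lower, 69 were also lower (2.4 for independent lists). Across all genes r was 0.366 and rho 0.18, and r was 0.216 and 0.08 without eat-2(ad1116) replicate 1 and dis-3(L75Q) replicate 3. Of the genes higher in eat-2(ad1116), 13 were lower in the double mutant against eat-2(ad1116), among them tts-1, lipl-1, lipl-2 and fmo-2 (1.31 for independent lists). The 13 also hold F47H4.2, fbxa-136 and Y20C6A.1 of the chromosome V stretch almost without counts. Of the genes lower in eat-2(ad1116), 8 were higher in the double mutant against it, among them fat-7 and col-123 (0.53 for independent lists). The 8 also hold Y48G9A.11 and Y48G9A.6, neighbours on chromosome III (2112416 to 2116897 and 2117841 to 2119158). In eat-2(ad1116) Y48G9A.6 had 0 counts and Y48G9A.11 0.187 CPM, against 1.75 CPM in wild type and 2.08 in the double mutant. A variant of the eat-2(ad1116) strain there was not tested. The comparisons of eat-2(ad1116) against wild type and of the double mutant against eat-2(ad1116) share the eat-2(ad1116) libraries. In 20 simulations of unchanged groups the number of such opposite calls was at most 1, the observed correlation was -0.342 against -0.499 simulated, and the covariance was -0.127 against -0.077, a difference of -0.05. Those simulations held no eat-2(ad1116) effect, so few genes could be called in them, and the count of at most 1 is no test of the excess. The 3 shared libraries could not be split, and part of the excess may come from sharing them.

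**Figure D3:**
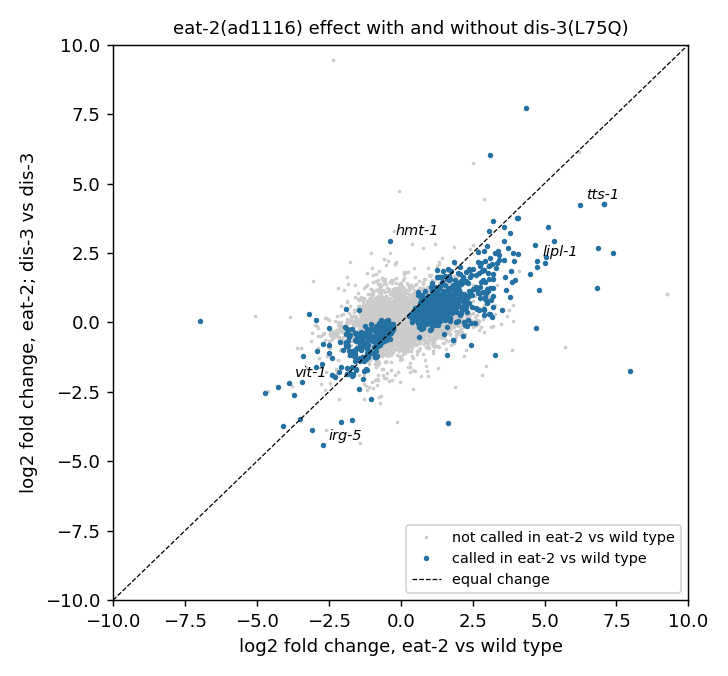
Log2 fold change of each tested gene for eat-2(ad1116) against wild type (x axis) and for the double mutant against dis-3(L75Q) (y axis), with the 1009 genes called in the first comparison in blue and a dashed line of equal change. Of the blue points, 95% have the same sign on both axes, and hmt-1 is raised on the y axis alone.

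In the double mutant against wild type, tts-1 (26.2-fold), clec-61 (13.9-fold), lips-6 (11.3-fold) and col-41 (15.5-fold) rose. The genes acdh-2 (log2 -3.62 ± 0.35), vit-1 (log2 -3.61 ± 0.71), grl-27 (8.29-fold) and rnf-126 (6.41-fold) fell. The test called 695 genes, 413 higher and 282 lower, and the share that was higher went from 59.4% to 76.8% without scaling. Fasting response genes had 9 of 46 higher and 2 lower (13 and 3 adjusted over the list alone), innate immune effectors 15 of 100 higher and 8 lower (23 and 14), DAF-16 targets 9 of 38 higher and 3 lower (15 and 5), neurons 5 of 39 higher (24 higher and 1 lower) and ribosome biogenesis 4 of 36 lower (19). Camera called 17 lists, 7 up and 10 down, and 0 with an estimated correlation (lowest adjusted p = 0.18), while the stage score differed by 2.21. With that score as a covariate camera called 21 lists, 13 of them among the 17. Of these 10 kept their direction and sperm, oocyte and germline genes changed theirs. The other 8 were collagens, up, and 7 down, ribosomal proteins, oxidative phosphorylation, the mitochondrial and endoplasmic reticulum stress responses, SKN-1 targets, autophagy and lysosome, and body wall muscle. Of the 17, molting (adjusted p = 0.095) and pharynx (0.06) lost the call. Fasting response (0.5) and innate immune effectors (0.9) lost it and turned from up to down. The count was 1798 with DESeq2, 1432 in a fit of these 6 libraries alone, 1046 without scaling, 2390 without wild type replicate 2, 240 and 277 without wild type replicates 1 and 3, and 268, 238 and 230 without double mutant replicates 1, 2 and 3. Calls for col-41, vit-1 and grl-27 were lost without any of those last 5 libraries (highest adjusted p = 0.18). With the stage score as a covariate 744 genes were called, 278 higher and 466 lower, 406 of them among the 695, and col-41 (adjusted p = 0.18) and grl-27 (0.062) were lost.

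The interaction asks whether the effect of dis-3(L75Q) differed between the wild-type and eat-2(ad1116) backgrounds, and 10 genes passed it, 6 higher and 4 lower. Each genotype was 1 strain, so a difference of strain and one of genotype are not separated. The hmt-1 transcript was low in dis-3(L75Q) alone, at 9.32 ± 0.7 CPM against 87.6 ± 3.2, 67.7 ± 3 and 71.3 ± 3.2 in wild type, eat-2(ad1116) and the double mutant (log2 interaction 3.31 ± 0.12, adjusted p = 4.1e-07). The essential gene let-355 was likewise low in dis-3(L75Q), at 38 ± 2.3 CPM against 66.5 to 78.6 on average in the others (0.98 ± 0.14, adjusted p = 0.037). The scb-1 transcript was at 2.9 ± 0.66 CPM in wild type and at 18.9 ± 1.5, 24.4 ± 4.4 and 23.2 ± 0.51 in the 3 mutants (-2.77 ± 0.26, adjusted p = 0.0026). The effect of dis-3(L75Q) on tts-1 (-2.01 ± 0.26, adjusted p = 0.034) and lipl-1 (-2.54 ± 0.36, adjusted p = 0.039) was a fall in the eat-2(ad1116) background, where both transcripts were high. The desaturase genes fat-6 (0.11 ± 0.2), fat-7 (0.25 ± 0.2) and fat-5 (0.11 ± 0.24) did not pass it.

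Camera called 16 lists for the interaction, 8 up and 8 down, with sperm (median 1.3) and innate immune effectors (-0.43) among them, and 0 with an estimated correlation (lowest adjusted p = 0.72). The stage covariate gave 12 lists, 7 of them among the 16. Of these 5 kept their direction, and ribosomal proteins and body wall muscle changed theirs. The other 5, all up, were tRNA synthetases, oxidative phosphorylation, endoplasmic reticulum stress, fatty acid synthesis and intestine. The 31 lists without a called gene in edgeR held 1357 genes, of which 118 had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. In simulated data, whose genes were drawn without correlation, this test recovered 12% of 2-fold and 54% of 4-fold interactions (50 genes of each size). The count was 52 with DESeq2, 6 with limma-voom, 2214 without eat-2(ad1116) replicate 1, 6 without wild type replicate 1 or eat-2(ad1116) replicate 2, 3 without wild type replicate 3, and 4 without dis-3(L75Q) replicate 1 or 2, eat-2(ad1116) replicate 3 or any double mutant library. Of the 5 named genes, hmt-1 and scb-1 held with any library left out, while let-355 was lost without any 1 library other than wild type replicate 2 or eat-2(ad1116) replicate 1, lipl-1 without any other than dis-3(L75Q) replicate 3 or eat-2(ad1116) replicate 1, and tts-1 without any other than those 3 or eat-2(ad1116) replicate 2 (highest adjusted p = 0.24). With the stage score as a covariate tts-1 and lipl-1 missed the threshold (log2 -1.95 and -2.02, adjusted p = 0.066 each).

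**Figure D4:**
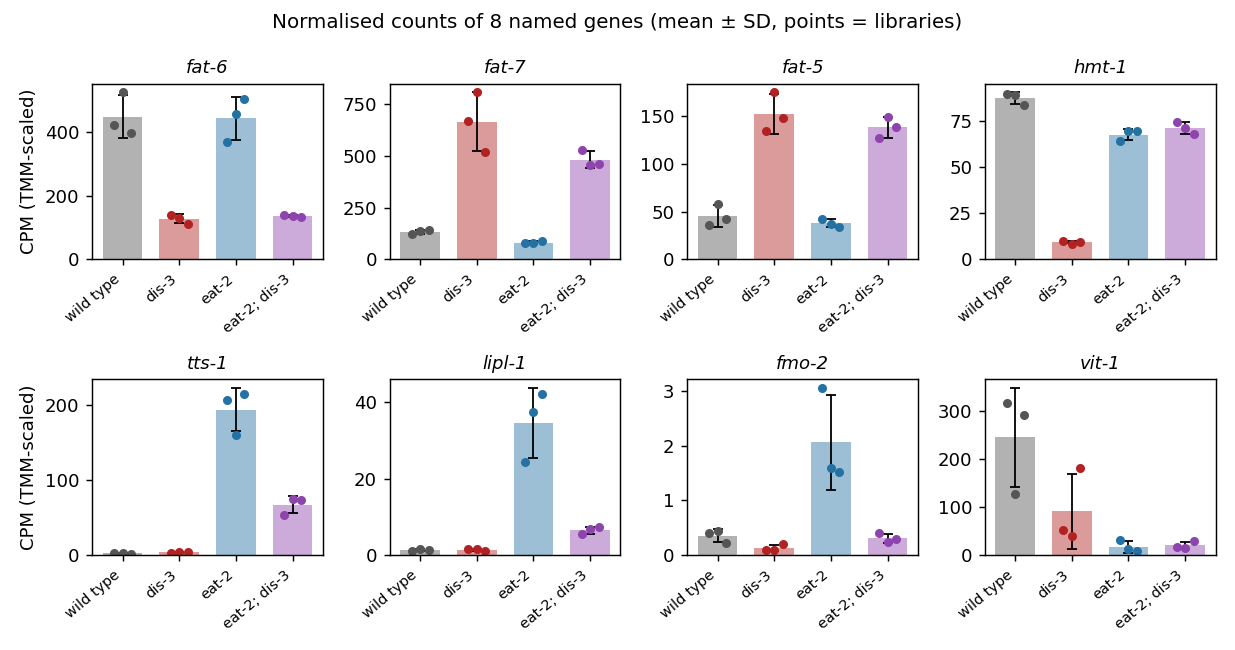
Normalised counts (CPM, y axis, from 0) of 8 named genes by genotype, with bars for the mean, error bars for the SD and points for the 3 libraries. The fat-6, fat-7 and fat-5 levels follow dis-3(L75Q) in both backgrounds, hmt-1 is low in the dis-3(L75Q) single mutant, and tts-1, lipl-1 and fmo-2 are highest in eat-2(ad1116).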

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

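Apart from those of other splits, the tests in this part (the chromosome V interval, the F-box family, swapped libraries, developmental pace, the stage score, shared fat-6 and fat-7 reads and strain variants) were chosen only after the result was seen.

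In 10 genes the effect of dis-3(L75Q) differed between the wild-type and the eat-2(ad1116) background by the edgeR interaction test. The log2 interactions were 3.31 for hmt-1, 0.98 for let-355, -2.77 for scb-1, -2.01 for tts-1 and -2.54 for lipl-1. The other 5 lie outside the naming rule and were chosen after their values were seen. They were T24C12.3 (3.54 ± 0.31, adjusted p = 0.0017), at 3.4 CPM in dis-3(L75Q) and 33.5 to 40.8 CPM on average in the other genotypes, and C09D4.4 (1.43 ± 0.16, adjusted p = 0.0078), at 24.9 against 65.2 to 68.5 CPM. The others were fbxa-192 (2.12 ± 0.29, adjusted p = 0.037), Y48G9A.11 (3.49 ± 0.48, adjusted p = 0.037), at 0.187 CPM in eat-2(ad1116) and 1.68 to 2.08 CPM elsewhere, and T10D4.6 (-1.22 ± 0.17, adjusted p = 0.042), at 35.8 CPM in dis-3(L75Q), 15.5 in wild type and 16.3 in the double mutant. A variant carried by the dis-3(L75Q) strain and absent from the double mutant strain would give the same values for hmt-1, let-355, T24C12.3 and C09D4.4, which were low in that strain alone. The design with 1 strain per genotype does not separate it from an interaction. C09D4.4 (chromosome I, 5479488 to 5484661) lies beside let-355 (5472325 to 5479438). Of 100 splits of the libraries, the real one included, 4 gave at least as many interaction genes as the real one (10, highest other 5454). The splits also break up the effect of dis-3(L75Q) within each background. They therefore do not decide whether chance could give 10 genes, and the high split points to a structure of the samples.

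The first pattern is the shift of molting, oocyte, sperm and yolk lists in dis-3(L75Q) against wild type. A swap of wild type replicate 2 with dis-3(L75Q) replicate 3 is argued against by 847 counts over the chromosome V interval in the former and 0 in the latter, and a swap with eat-2(ad1116) replicate 1 by tts-1, which was 65.7 times the highest wild-type library there. The stage score spanned 3.16 log2 units within wild type, more than the difference of 2.43 between the genotypes, so varied developmental stage at harvest is a candidate explanation. A change of developmental pace by dis-3(L75Q) cannot be told apart from it, since the exact permutation p was 0.2 with 3 libraries against 3, although in the eat-2(ad1116) background the score did not rise with dis-3(L75Q) (difference -0.175, exact permutation p = 1). For the called genes, without 11 that had a group at 0 counts, the median absolute log2 change of 80 genes went from 1.76 to 1.43 with the stage score as a covariate, a ratio of 0.81. Of the 91, 56 were still called, while irg-5, clec-3, acdh-2, cyp-34A9, cpt-4 and clec-82 were not. Called genes vary little within genotypes, where the score spread widely, so their choice favours genes that do not follow the score. The ratio therefore does not decide how far stage contributed.

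The second pattern is the chromosome V stretch without counts in both dis-3(L75Q) strains. Lower expression of the F-box family is argued against by a median log2 change of 0.08 in dis-3(L75Q) and -0.1 in the double mutant over 140 F-box and skr genes elsewhere. Reads moving to near-identical copies cannot be told apart, since the summed level of 150 F-box and skr genes outside the stretch changed by -25.6 CPM (SE 29.7) in dis-3(L75Q), against 29.1 CPM lost inside it, and copies of its other genes were not searched, although in the double mutant the sum changed by -59.9 CPM against 56.2 lost. A deletion or a diverged sequence in the strain background stays open and untested, since the stretch was picked for its low counts and the highest count of 3 in the 6 libraries restates that choice. The stretch and its surroundings held 17.6% of the 91 called genes (16, all lower) and 0.209% of the tested genes, a window also picked after its calls were seen, and the design cannot separate the strain from dis-3(L75Q).

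The third pattern is low fat-6 with high fat-7 and fat-5 in both dis-3(L75Q) strains. Developmental stage is argued against by the same changes in the eat-2(ad1116) background, where the score differed by -0.175. With the score as a covariate the changes kept 0.92 or more of their size, a ratio that the choice of called genes favours. Reads exchanged between fat-6 and fat-7 stay open, because their sum was 1.36 times that of wild type in dis-3(L75Q) and 1.18 times that of eat-2(ad1116) in the double mutant (exact permutation p = 0.2 each), and such an exchange could not raise fat-5. A strain variant at or near fat-6 could also account for the fall and cannot be told apart from an effect of dis-3(L75Q), since both came with the same strain and the change differed between backgrounds by 0.11 on the log2 scale. The fat-5 gene lies near the chromosome V stretch almost without counts, past its right end at 17551209. A strain variant in that region cannot be told apart for fat-5 either. An effect of dis-3(L75Q) itself remains untested.

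With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 91 genes in dis-3(L75Q) against wild type and the highest other 522 (2 of 10 as large). It called 1009 in eat-2(ad1116) against wild type and the highest other 4371 (2 of 10). The counts were 57 and 1 for the double mutant against eat-2(ad1116), 202 and 0 against dis-3(L75Q) and 695 and 2 against wild type (1 of 10 each). Every other split mixes the 2 genotypes within a group, so differences between them become spread within groups and lower its count. The low counts of other splits are therefore no test of chance. The splits with 522 and 4371 genes put wild type replicates 1 and 3 with dis-3(L75Q) replicate 3 or with eat-2(ad1116) replicate 1, which points to a structure of the samples along the stage score. For lists, as many as in the real split were called in 3 of 10 splits (18, highest other 19), 3 (19 and 23), 10 (7 and 23), 5 (15 and 21) and 2 (17 and 17) in the same order, and in 40 of 100 for the interaction (16 and 24), where chance is not excluded.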

How the results depend on the processing

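The stage-score covariate and the omission of 3 libraries were chosen after seeing the data. Of 1715 values of named genes under alternatives, 0 changed direction, 1387 stayed on their side of the threshold and 328 lost the call, 164 of them among 594 with 1 library left out. The adjusted p under 0.01 and the 2-fold minimum, with 94 values each, reuse the main log2 change and could not turn it. The genes were also named for calls in these same libraries, so the absence of turned directions is a weak check. Counts of called genes are given in the order dis-3(L75Q) against wild type, eat-2(ad1116) against wild type, the double mutant against eat-2(ad1116), dis-3(L75Q) and wild type, and the interaction, and the cause was not tested unless stated. They were 91, 1009, 57, 202, 695 and 10. With DESeq2 they were 338, 2284, 174, 608, 1798 and 52. An adjusted p under 0.01 gave 44, 238, 28, 82, 212 and 4, as a stricter threshold must give fewer. Leaving out 1 library gave 49 to 1306, 298 to 6161, 29 to 255, 74 to 170, 230 to 2390 and 3 to 2214. Without the 3 libraries apart on the stage score they were 8442, 9589, 4117, 4094, 7683 and 8677. These counts are inflated because the omission removes spread within groups by its construction. It also leaves wild type at -2.281 and -3.076 on the score and both single mutants at 1.199 to 1.623, so stage and genotype cannot be told apart there. A fit of the 6 libraries compared moved 3 counts by over 1.5 times, to 30, 84 and 31, and that of the double mutant against wild type to 1432. Without scaling 1714 genes were called in eat-2(ad1116) and 1046 in the double mutant against wild type. At least 2-fold were 570 and 439. The stage score as a covariate gave 176 and 768 for the double mutant against eat-2(ad1116) and dis-3(L75Q), and limma-voom 6 for the interaction. Replicate numbers did not pair the libraries (7 of 18 same-number pairs over 0.1, -0.626 to 0.424, 2 of 12 libraries closest to their own number). The replicate block gave 62, 496, 25, 115, 392 and 4 genes and changed no list count by over 1.5 times. Lists called by camera were 18, 19, 7, 15, 17 and 16. They were 0 in each with an estimated correlation and 0, 11, 1, 5, 10 and 1 with fry. The stage covariate gave 5 for dis-3(L75Q), and the double mutant against eat-2(ad1116) had 7 to 18 with 1 library left out and 20 without the 3 libraries. The correlation of the eat-2(ad1116) effects (0.366) was 0.08 to 0.497 with 1 library left out and -0.159 without the 3 libraries. That of the dis-3(L75Q) effects (0.298) was -0.151 to 0.458, lowest without eat-2(ad1116) replicate 1, and -0.272 without the 3 libraries. Tests on log2(TPM + a pseudocount) were not run, since the files used here have no such values. Depth limits genes near the floor of 3 counts, such as the eat-2 transcript.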

Other observations

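The gene-class, RNA exosome and shared-response tests were chosen only after the results were seen. Gene classes by name, 142 of them with at least 10 tested members, were compared with the called genes by Fisher's exact test, adjusted over 1704 tests. The test takes genes as independent, although their calls come from the same libraries. Its p-values therefore overstate the evidence where members of a class move together, and the classes were not tested with the stage score. In eat-2(ad1116) against wild type, 15 of 30 flp genes, which encode FMRFamide-like neuropeptides, were higher (1.3 by chance, adjusted p = 4.6e-10), as were 14 of 65 nlp neuropeptide-like genes (adjusted p = 0.00013), 22 of 134 clec C-type lectin entries (adjusted p = 2.4e-05) and 8 of 18 nspc genes, whose near-identical members can share reads (adjusted p = 9e-05). The name clec-15 stands for 2 of the 22 entries, with equal mean levels, and 7 of the 134 clec entries were lower (adjusted p = 1, with clec-209 for 2 of them). Also higher were 10 of 67 cyp cytochrome P450 genes (adjusted p = 0.045). Lower were 10 of 65 ugt UDP-glucuronosyltransferase genes (adjusted p = 0.00051) and 4 of 13 rpn proteasome genes (adjusted p = 0.019). In dis-3(L75Q) against wild type, 7 of 134 clec entries were higher (adjusted p = 0.00019) and 5 of 131 fbxa genes lower (adjusted p = 9e-04), 3 of them inside the chromosome V interval. In the double mutant against dis-3(L75Q), 4 of 38 gst genes (adjusted p = 0.021), 3 of 10 dod genes (adjusted p = 0.0075), 3 of 12 asp aspartyl protease genes (adjusted p = 0.011), 5 of 65 ugt genes (adjusted p = 0.017) and 7 of 134 clec entries (adjusted p = 0.011, the name clec-209 standing for 2 of them) were lower. Higher were 4 of 67 cyp genes (adjusted p = 0.041) and 4 of the clec entries (adjusted p = 0.35).

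Ribosomal RNA made up 8.08 ± 1.2% of counts in wild type, 8.71 ± 0.75% in dis-3(L75Q), 8.01 ± 0.6% in eat-2(ad1116) and 7.16 ± 0.94% in the double mutant (SD, 3 libraries each). Small nucleolar RNA made up 0.118 ± 0.034%, 0.0772 ± 0.025%, 0.0674 ± 0.028% and 0.0723 ± 0.0094%, with an exact permutation p of 0.2 for each mutant against wild type.

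One hypothesis was that transcripts of the RNA exosome and other exonucleases rise where DIS-3 is altered. Their median log2 change was -0.13 in dis-3(L75Q) against wild type and -0.01 in the double mutant against eat-2(ad1116), with 5 and 11 of 24 members positive. The upper quartiles were -0.04 and 0.07. These values argue against a marked rise of the list as a whole, while a small rise or one of single members stays open. Another was that the double mutant loses part of the eat-2(ad1116) response across all its genes. The median rise in the double mutant against dis-3(L75Q) over that in eat-2(ad1116) against wild type was 0.39 for the 664 genes chosen on the latter and 0.85 for the 89 chosen on the former, so the ratio depended on the choice of genes and does not decide it.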
